A study of Mus musculus with 20 samples.

How the data were processed

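Total RNA was extracted from SV40-immortalized mouse embryonic fibroblasts with both AMPK catalytic subunit genes deleted, and biotin-labelled cRNA was hybridised to the Affymetrix MG-430 PM array strip, per the labels' protocols. The 20 arrays fall into 7 groups given by the labels: a control at 0 h (3 arrays) and 1 mM AICAR for 1, 2, 4, 12 and 24 h (3 arrays each) and 8 h (2 arrays). The deposited values are a table of 45141 probe sets by 20 arrays, taken as log2 signal: their highest value, 13.5, exceeds the natural log of a 16-bit scanner maximum (11.1) and lies below its log2. How the authors corrected the background, summarised and normalized these values is not given in the sources used here. Array medians differed by 0.159, under the 0.2 set beforehand for renormalizing, so the log2 values were used as deposited. The filter cutoff, the nonspecific control level (median 3.71, 95th percentile 5.08) and array medians stand in for depth.

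Of the probe sets, 104 are array controls and were left out of tests. The platform annotation lists 29449 probe sets, 28898 with a single gene symbol and 551 with several, and 15692 of the table's probe sets are not listed, controls included. Probe sets with several symbols or none were not named. Symbols were updated through gene identifiers for 28689 probe sets with the GRCm38.p6 gene table, used for names alone; no coordinates are given because no genome build is named in the sources used here. The probe set with the highest mean over the arrays stood for each of 17097 genes. Genes whose highest group mean was not above the 40th percentile of all values (4.81) were left out, which removed 4153 and left 12944.

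The comparisons were each time in AICAR against 0 h, late (8, 12 and 24 h) minus early (1, 2 and 4 h), and a moderated F test over the 6 times. All were made with limma 3.58.1 in R 4.3.3 by lmFit and eBayes in a single fit over the 20 arrays, two-sided, with Benjamini-Hochberg adjustment over the genes tested within each comparison and a threshold of 0.05 on the adjusted p. Fold changes are differences of group means of log2 values, with standard errors from the fit. There were 13 residual degrees of freedom. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

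A total of 33 gene lists (657 members, 594 named on the array) were fixed before the data were examined from general knowledge, 5 of them markers of macrophages, epithelial, endothelial, adipose and muscle cells. The 30 lists with at least 5 tested members were tested with camera (preset correlation 0.01), adjusted over lists and times together, and for late minus early over lists. The macrophage, endothelial and adipocyte marker lists had under 5 tested members. Camera with an estimated correlation and fry were alternatives.

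Genes were named by a rule fixed before the data were examined. For each comparison these were the 10 largest rises and 10 largest falls past the threshold whose arrays did not overlap those of the other side, up to 4 members of each list past it (else the 2 with the largest t, as values), and Prkaa1, Prkaa2, Lats1, Lats2, Txnip, Cdkn1a, Adk and Atic. Riken and Gm loci were skipped. Atic has no probe set with that single symbol here. Genes named in the text are a selection from that rule, except where it is said that they were chosen after their values were seen.

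The fit was tested on simulated data made from the real means and spreads of the 12944 genes. With 100 genes changed by 1 on the log2 scale, 99 were recovered at 24 h against 0 h, and 98 at 8 h, where 2 arrays stand against 3. With 100 changed by 0.5, 74 were recovered at 24 h and 58 at 8 h. Of the genes called, unchanged ones were 17 of 191 at 1 h, 12 of 168 at 8 h and 8 of 181 at 24 h. A list lowered by 0.3 at 24 h was called, and 0 other list and time pairs were. The simulated genes varied independently of each other, so this does not show how often lists are called wrongly when genes vary together.

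Alternatives fixed beforehand were quantile normalization, median centring, no filter, a filter at the 60th percentile, the mean of all probe sets of a gene, no _x_ or _s_ probe sets, each probe set on its own, trended and robust variance, array weights, the replicate number as a block, stricter thresholds, a fit of the compared groups alone, and leaving out each array in turn. Added after the data were seen were each array's interquartile range as a covariate and leaving out the 2 arrays with the highest medians.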

Results

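Gene expression was measured in SV40-immortalized mouse embryonic fibroblasts that lack both catalytic subunits of AMP-activated protein kinase (AMPK), the energy-sensing kinase, which are encoded by Prkaa1 and Prkaa2. The cells were exposed to 1 mM AICAR, a cell-permeable adenosine analog that is phosphorylated inside cells to the AMP mimic ZMP and is widely used to activate AMPK. RNA was hybridised to 20 Affymetrix mouse arrays. There were 3 control arrays at 0 h without AICAR, 3 arrays at each of 1, 2, 4, 12 and 24 h and 2 arrays at 8 h. The question was which transcripts change with AICAR when AMPK is missing. The controls were taken at 0 h, so hours in AICAR and hours in culture changed together in each comparison. Array medians lay between 5.16 and 5.32 on the log2 scale, and the number of arrays limits the precision. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these arrays, which may be technical.

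The probe set for Prkaa1 gave a log2 signal of 8.19 ± 0.06 (SD, n = 3) in the controls, and its changes at the 6 times did not pass the test. Prkaa2 had a control mean of 5.63. Its difference of 0.61 ± 0.20 (SE) at 12 h passed the test (limma adjusted p = 0.0359), but did not pass without each of the 3 control arrays in turn, or without AICAR 12h replicate 1, where it was 0.25. No wild-type array was analysed here and the positions of these probes relative to the deleted parts are not given in the sources used here, so both values check nothing about the knockout.

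Expression differed among the 7 times for 6260 of 12944 genes (limma moderated F test, adjusted p under 0.05). Against 0 h, 62 genes changed at 1 h, 190 at 2 h, 1564 at 4 h, 1336 at 8 h, 3068 at 12 h and 5229 at 24 h. Of these, 11, 21, 46, 32, 117 and 499 also changed at least 2-fold. The 8 h group had 2 arrays, and its count was 250 without AICAR 8h replicate 1, 700 without AICAR 8h replicate 2 and 780 without control 0h replicate 3. At 1 h the count was 41 and 31 without control 0h replicates 1 and 2, and 30 and 18 without AICAR 1h replicates 2 and 3. At 2 h it was 82 and 78 without those 2 controls and 78, 102 and 109 without AICAR 2h replicates 1, 2 and 3, and at 4 h it was 904 and 939 without the 2 controls.

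**Figure D1:**
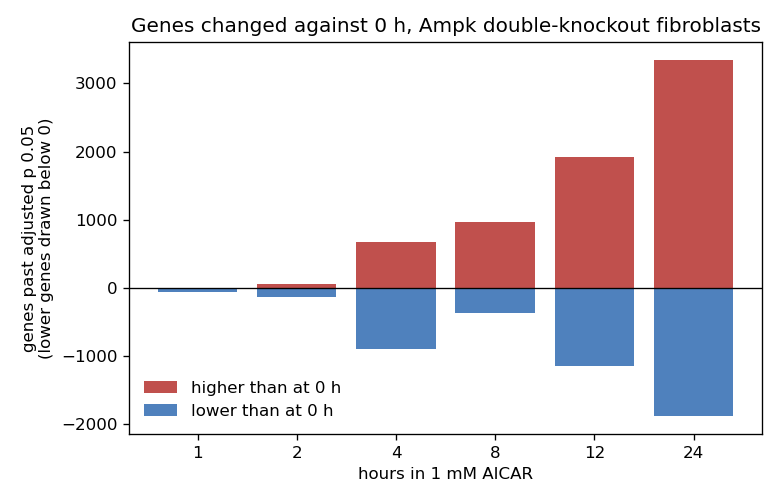
Number of genes (y axis) past a limma adjusted p of 0.05 against the 0 h controls at each time in AICAR (x axis, hours, evenly spaced), with higher genes above 0 and lower genes below. The bars at 1 h show 1 higher and 61 lower gene, and those at 24 h show 3342 higher and 1887 lower genes.

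After 1 h, 61 of the 62 changed genes were lower than at 0 h. The share depended on the setting: 26 were higher and 84 lower with quantile normalization, 23 of 153 were higher with each array's interquartile range as a covariate, chosen after the data were seen, and 82 of 421 with array weights. The largest falls were in the cold-inducible RNA-binding protein gene Rbm3, by 1.88 ± 0.25 on the log2 scale (SE; adjusted p = 0.0016), and in Zfp719 (-1.43), Rgs16 (-1.27), a regulator of G-protein signalling, and Gadd45b (-1.13), a stress-response gene. Spry4, a feedback inhibitor of receptor tyrosine kinase signalling, Fosl2, an AP-1 subunit, and Ddit4, an inhibitor of mTORC1 signalling, fell by 1.10, 1.03 and 1.02. Disp1 rose by 1.11 (adjusted p = 0.0188) from a control signal of 4.73, below the background level of 5.08 (95th percentile of the non-specific control probe sets), but did not pass without any single array of the 2 groups, nor did Zfp719, Rgs16 and Spry4 without AICAR 1h replicate 3. With the mean of all probe sets of a gene, Spry4 and Fosl2 did not pass (-0.25 and -0.42), and Zfp719 and Rgs16 were -0.76 and -0.75.

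Of 25 immediate early genes, which respond to stimuli within minutes, 7 fell and 0 rose at 1 h (14 fell adjusted over the list alone), among them Dusp1 (-0.94), Klf2 (-0.93), Dusp6 (-0.93) and Egr1 (-0.86). The list was shifted down (camera adjusted p = 1.73e-25; adjusted p = 0.0545 with an estimated correlation). Of 16 NF-kB and inflammatory genes, 3 fell (8 adjusted over the list alone), namely the chemokine gene Cxcl1 (-0.93, to 4.73, below the background level), the inhibitor gene Nfkbia (-0.68) and the prostaglandin synthase gene Ptgs2 (-0.62; -0.14 with the mean of its probe sets). This list was also shifted down (camera adjusted p = 4.84e-10; adjusted p = 0.167 with an estimated correlation). Among 17 genes of cholesterol synthesis and uptake, Insig1, a regulator of sterol synthesis, fell by 0.69, and 10 fell adjusted over the list alone. The list median was -0.27 (camera adjusted p = 3.96e-16; adjusted p = 0.1002 with an estimated correlation). Dusp6, Egr1, Cxcl1, Nfkbia, Ptgs2 and Insig1 did not pass without AICAR 1h replicate 3. In all, 13 of 30 lists were shifted at 1 h, 12 of them down, and 0 held with an estimated correlation, where the lowest adjusted p was 0.0545. AICAR 1h replicate 3 had the lowest 99th percentile (11.8) and maximum (13.1) of all arrays, against a 99th percentile of 12.0 in each control. The 67 cytosolic ribosomal protein genes, chosen after the results were seen, had a median control signal of 12.98 and a median change of -0.11 at 1 h. Quantile normalization, which gives all arrays the same distribution, left 60 of the 62 genes called at 1 h past the test. Without AICAR 1h replicate 3, 18 genes passed, all of them lower. This argues against that array's upper range as the whole cause of these calls. How much of the size of each fall comes from it was not tested.

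After 2 h, 61 genes were higher and 129 lower, against 299 and 319 with the interquartile range covariate, 30 and 111 with median centring, 38 and 44 without control 0h replicate 1 and 26 and 106 without replicate 3. Taf15, which encodes an RNA-binding protein of the FET family, rose by 1.69 ± 0.28 (SE; adjusted p = 0.00422), and Rbm15, another RNA-binding protein gene, rose by 0.94. Other rises included the zinc finger genes Zfp948 (0.98) and Zbtb7a (0.88), Zc3h12c (0.86) and Fubp1 (0.80), a single-strand DNA-binding regulator of Myc. With the mean of all probe sets, Zbtb7a and Fubp1 did not pass (0.39 and 0.66), and Taf15, Zfp948 and Zc3h12c were 1.00, 0.47 and 0.45 above the controls. Zc3h12c did not pass without AICAR 2h replicate 1 or control 0h replicate 3. Chac1, a glutathione-degrading enzyme induced by ATF4, fell by 1.86 ± 0.25 (SE; adjusted p = 0.000802). Fam43a (-1.83, to 4.88, below the background level), Nabp1 (-1.76), a single-stranded DNA-binding protein gene, and Ppp1r10 (-1.43), a regulatory subunit of protein phosphatase 1, fell as well.

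At 2 h 9 of the 25 immediate early genes fell (14 fell and 4 rose adjusted over the list alone), including Dusp4 (-1.13) and Egr1 (-1.08), with camera adjusted p = 3.12e-09 and adjusted p = 0.286 with an estimated correlation. Of the 16 NF-kB and inflammatory genes 7 fell (9 adjusted over the list alone), including Ccl2 (-0.85) and Tnfaip3 (-0.81). Their shift had camera adjusted p = 3.08e-11 and adjusted p = 0.133 with an estimated correlation. The 31 genes of ATF4 and the integrated stress response had 5 falls and 0 rises (6 falls adjusted over the list alone), with Chac1, Ddit3 (-1.10) and the arginine transporter gene Slc7a1 (-0.51) among them (camera adjusted p = 0.00214; adjusted p = 0.691 with an estimated correlation). Txnip, which encodes a regulator of thioredoxin and glucose uptake, rose by 0.73 ± 0.13 (SE; 0.44 with the mean of its probe sets, where Tnfaip3 was -0.50). Slc7a1 did not pass with the mean of its probe sets (-0.19), nor Ccl2 and Txnip without control 0h replicate 1.

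After 4 h, 671 genes were higher and 893 lower. Which direction held more genes depended on the setting: 1221 were higher and 1029 lower with each array's interquartile range as a covariate, chosen after the data were seen, 494 and 410 without control 0h replicate 1, 486 and 453 without control 0h replicate 2, 417 and 982 without control 0h replicate 3, and 337 and 761 with median centring. Taf15 stood 2.09 ± 0.28 (SE) above the controls, and the RNA-binding protein genes Rbm15, Rbm4 and Rbm14 rose by 1.41, 1.18 and 1.04. Oga, the enzyme that removes O-GlcNAc from proteins, rose by 1.02, and Zbtb7a by 1.10 (0.44, not past the test, with the mean of its probe sets). Ppp1r10 fell by 2.36 ± 0.16 (SE; 5.13-fold), Nabp1 by 1.93, the transcription factor gene Runx1 by 1.66 and the tubulin-folding cofactor gene Tbcc by 1.47. With the mean of all probe sets, Taf15 was 1.19, Oga 0.64, Runx1 -0.55 and Tbcc -0.95 from the controls. Hbegf, a growth factor of the EGF family, fell by 1.30 and did not pass without any single control array or without AICAR 4h replicates 2 or 3.

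Of the 16 NF-kB and inflammatory genes 8 fell at 4 h (9 adjusted over the list alone), led by Ptgs2 (-0.92; -0.42 with the mean of its probe sets) and Ccl2 (-0.89), with camera adjusted p = 2.6e-05 and adjusted p = 0.405 with an estimated correlation. Of 13 TGF-beta and BMP targets 5 fell and 1 rose (5 and 1 adjusted over the list alone). Smad6 fell by 0.88, Id1 by 0.88 (0.55 without AICAR 4h replicate 1) and Id4 by 0.80 (camera adjusted p = 0.0033; adjusted p = 0.405 with an estimated correlation). Of 29 genes of G2/M and mitosis 7 rose (9 rose and 1 fell adjusted over the list alone), including the proliferation marker Mki67 (0.38; 0.25 with array weights) and the hyaluronan receptor gene Hmmr (0.34), with camera adjusted p = 0.00314 and adjusted p = 0.814 with an estimated correlation. Of 20 genes of autophagy and the lysosome 4 rose (4 adjusted over the list alone), among them Fnip1 (0.90), Fnip2 (0.71) and Flcn (0.37), whose proteins form the folliculin complex (camera adjusted p = 0.0372; adjusted p = 0.814 with an estimated correlation). Fnip1 did not pass with the mean of its probe sets (0.73) or without _x_ and _s_ probe sets (0.32). Flcn, Id4, Mki67 and Hmmr did not pass without some single arrays, among them control 0h replicate 1 for Flcn, Id4 and Mki67 and replicate 2 for Hmmr.

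After 8 h, 969 genes were higher and 367 lower, against 594 and 187 with median centring, 1466 and 905 with array weights and 472 and 308 without control 0h replicate 3. Klf4 and Klf2, Kruppel-like transcription factor genes, rose by 1.53 ± 0.11 and 1.31 ± 0.16 (SE). Rhob, a small GTPase gene, rose by 1.39 ± 0.13, and Senp8, which encodes a NEDD8 protease, by 1.48 (0.58, not past the test, with the mean of its probe sets). The linker histone gene H1f2 fell by 1.33 ± 0.11 (SE; adjusted p = 2.64e-06), the snoRNA host gene Taf1d by 1.22, the MAP kinase phosphatase gene Dusp6 by 1.03 and the protocadherin gene Pcdh18 by 1.04 (0.45 with the mean of its probe sets). The RNA helicase gene Ddx6 fell by 1.31, and by the mean of its probe sets was -0.96, not past the test. Of 20 extracellular matrix and myofibroblast genes 5 fell (8 adjusted over the list alone), including Fbln5 (-0.38) and Dcn (-0.37), with camera adjusted p = 2.34e-05 and adjusted p = 0.615 with an estimated correlation. Of 11 heat shock genes 3 rose (3 adjusted over the list alone), led by Hspa1b (0.61), with camera adjusted p = 0.0445 and adjusted p = 0.738 with an estimated correlation. Senp8, Fbln5 and Dcn did not pass without AICAR 8h replicate 1, nor Fbln5 with the mean of its probe sets (-0.21).

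After 12 h, 1918 genes were higher and 1150 lower, against 1239 and 1127 without control 0h replicate 3, 1262 and 864 without AICAR 12h replicate 1, 2456 and 1733 with the interquartile range covariate and 2706 and 1939 with array weights. Hsd3b7, a bile acid synthesis enzyme, rose by 1.80 ± 0.10 (SE; adjusted p = 3.08e-09), Pxylp1 by 1.82, Klf4 by 1.76, Rhob by 1.54 and Apol9a by 1.63. Ccdc28b rose by 1.48, but differed by 0.89 with the mean of its probe sets and by -0.10 without _x_ and _s_ probe sets, whose probes can match several transcripts. Rgs16 fell by 2.12 ± 0.20 (SE; 1.39 with the mean of its probe sets), Fst, which encodes the activin-binding protein follistatin, by 1.91, Dusp6 by 1.84, H1f2 by 1.76 and the histone gene H2bc4 by 1.58. Of 21 interferon-stimulated genes 10 rose and 0 fell (11 rose adjusted over the list alone), among them Gbp2 (1.05), the RNA sensor gene Ifih1 (0.90) and Ifit1 (0.84). Their median change was 0.29 (camera adjusted p = 0.000586; adjusted p = 0.476 with an estimated correlation). Of 20 genes of ribosome biogenesis 11 fell and 0 rose (12 fell adjusted over the list alone), including Ddx21 (-0.62; -0.31 with the mean of its probe sets) and Nop56 (-0.55), with camera adjusted p = 5.27e-07 and adjusted p = 0.223 with an estimated correlation.

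After 24 h, 3342 genes were higher and 1887 lower, against 4189 and 2836 with array weights. The 3' minus 5' signal of the actin control probe sets, a sign of RNA quality, lay between 0.503 and 0.557 on these 3 arrays and between 0.383 and 0.458 in the controls, and was highest in AICAR 4h replicate 2 (0.689) and AICAR 8h replicate 2 (0.646). That of Gapdh overlapped (0.125 to 0.154 at 24 h and 0.0766 to 0.228 in the controls). The largest rises were in genes that interferon induces. Ifit1 rose by 4.99 ± 0.13 on the log2 scale (SE; adjusted p = 1.58e-14), Rtp4 by 4.81 ± 0.10, Apol9a by 4.08, Xaf1 by 3.78, the immunity-related GTPase gene Irgm2 by 3.68, and Trim30d by 3.40. With the mean of all probe sets, Rtp4, Xaf1 and Trim30d were 2.55, 2.05 and 1.36 above the controls. The control means of Ifit1 (4.73), Rtp4 (4.87), Irgm2 (4.68), Trim30d (4.51), Gbp3 (4.51), Usp18 (4.34) and Cd68 (4.77) lay below the 95th percentile of the non-specific control probe sets (5.08). Their differences are therefore differences of signal from background, and give no exact fold of the transcript. All 21 interferon-stimulated genes tested rose (21 adjusted over the list alone), with a median of 2.04, including the guanylate-binding protein gene Gbp3 (3.74), the antiviral gene Rsad2 (3.58) and the ISG15 protease gene Usp18 (3.54). The list's shift had camera adjusted p = 6.4e-21 and adjusted p = 0.0532 with an estimated correlation. Of 8 macrophage markers, Cd68, a lysosomal membrane protein gene, rose by 1.08, and Lyz2 and Ptprc differed by 0.07 and 0.11. Among markers of other cell types, the keratin gene Krt19 fell by 0.28, the muscle actin gene Acta1 by 0.45 and the endothelial receptor gene Kdr by 0.27, and the adipocyte marker Pparg differed by 0.01. The epithelial and muscle lists were not shifted (camera adjusted p = 0.613 and 0.307).

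**Figure D2:**
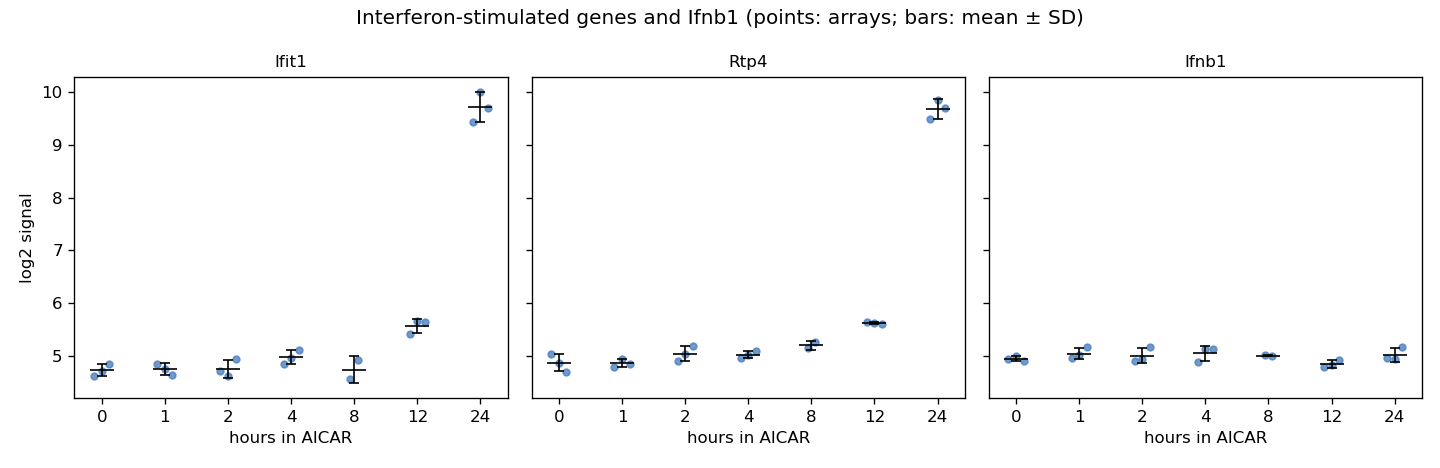
Log2 signal (y axis) of Ifit1, Rtp4 and the type I interferon gene Ifnb1 against hours in AICAR (x axis, evenly spaced), with a point for each array and bars for mean ± SD. Ifit1 rose by 4.99 and Rtp4 by 4.81 at 24 h from control signals below the background level of 5.08; Ifnb1, named after its values were seen, lay below that level in the controls (4.95) and at 24 h (5.02), so no change of it can be read.

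All 20 genes of ribosome biogenesis fell at 24 h (20 adjusted over the list alone), with a median of -0.82. The nucleolar RNA helicase gene Ddx21 fell by 1.16, Rrp12 by 1.10 and Rrs1 by 1.00 (camera adjusted p = 3.56e-15; adjusted p = 0.0545 with an estimated correlation). Of 13 genes of folate and serine one-carbon metabolism 11 fell and 0 rose (11 adjusted over the list alone), including the folate carrier gene Slc19a1 (-0.93), Mtap (-0.87), Aldh1l2 (-0.75) and the serine synthesis gene Psat1 (-0.67). The list median was -0.61 (camera adjusted p = 1.25e-07; adjusted p = 0.0722 with an estimated correlation). Of 20 genes of purine synthesis and salvage 12 fell and 2 rose (12 and 2 adjusted over the list alone). The AMP deaminase gene Ampd2 fell by 0.81 and Adsl, a purine synthesis enzyme, by 0.74, whereas Ampd3 rose by 0.61 (camera adjusted p = 0.000484; adjusted p = 0.615 with an estimated correlation). Of 14 pyrimidine synthesis genes 8 fell and 2 rose (8 and 2 adjusted over the list alone), with Dctd at -0.90 and Ctps at -0.79 (camera adjusted p = 0.00359; adjusted p = 0.691 with an estimated correlation). Adk, the adenosine kinase that converts AICAR to ZMP, fell by 0.25 ± 0.06 (SE; adjusted p = 0.00322).

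Of the 31 ATF4 and integrated stress response genes 18 fell and 4 rose at 24 h (19 and 4 adjusted over the list alone). The cystathionine lyase gene Cth fell by 1.53 and Chac1 by 1.47, while Atf3 rose by 1.51 (camera adjusted p = 2.34e-05; adjusted p = 0.427 with an estimated correlation). Of 13 TGF-beta and BMP targets 9 fell and 3 rose (9 and 3 adjusted over the list alone), led by Id1 (-2.05) and Id2 (-1.92), while Tgfbi rose by 1.31, or 0.66 without _x_ and _s_ probe sets (camera adjusted p = 0.00165; adjusted p = 0.352 with an estimated correlation). Of 20 extracellular matrix and myofibroblast genes 10 fell and 4 rose (12 and 4 adjusted over the list alone), with the smooth muscle actin gene Acta2 at -1.22 (-0.69 with the mean of its probe sets) and Tnc at -1.06 (camera adjusted p = 0.0153; adjusted p = 0.814 with an estimated correlation). Of 17 cholesterol genes 9 fell and 1 rose (9 and 1 adjusted over the list alone), including Insig1 (-0.92) and Sqle (-0.64), with camera adjusted p = 0.00314 and adjusted p = 0.738 with an estimated correlation. Outside the lists, Fst fell by 2.72 ± 0.13 (SE) to a signal of 4.95, below the background level, Pcdh18 by 2.60 (1.59 with the mean of its probe sets), the BMP antagonist gene Grem1 by 2.34 and the caveolae gene Cavin2 by 2.15. Ptgs2 fell by 2.14.

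Of 20 genes of autophagy and the lysosome 11 rose and 0 fell at 24 h (12 rose adjusted over the list alone), including the lysosomal channel gene Mcoln1 (1.37; 0.87 with the mean of its probe sets) and Rragd (1.03; 0.57), with camera adjusted p = 0.00211 and adjusted p = 0.605 with an estimated correlation. Of 20 genes for AMPK subunits and related kinases and their readouts 11 rose and 2 fell (12 and 2 adjusted over the list alone). Txnip rose by 2.32 ± 0.13 (SE), or 1.35 with the mean of its probe sets, and its relative Arrdc4 by 1.49 (camera adjusted p = 0.0445; adjusted p = 0.814 with an estimated correlation). Of 26 p53 targets 12 rose and 7 fell (12 and 7 adjusted over the list alone), with Pmaip1 at 1.14 and Psrc1 at -0.86 (-0.42 with the mean of its probe sets), and the list was not shifted (camera adjusted p = 0.520). Cdkn1a, the cell cycle inhibitor p21, rose by 0.53 ± 0.10 (SE), but the mean of its probe sets differed by 0.06. Of 29 genes of G2/M and mitosis 12 fell and 5 rose (13 and 5 adjusted over the list alone), including Kif23 (-0.93; -0.45 with the mean of its probe sets) and Aurka (-0.76), with camera adjusted p = 0.0461 and adjusted p = 0.870 with an estimated correlation.

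**Figure D3:**
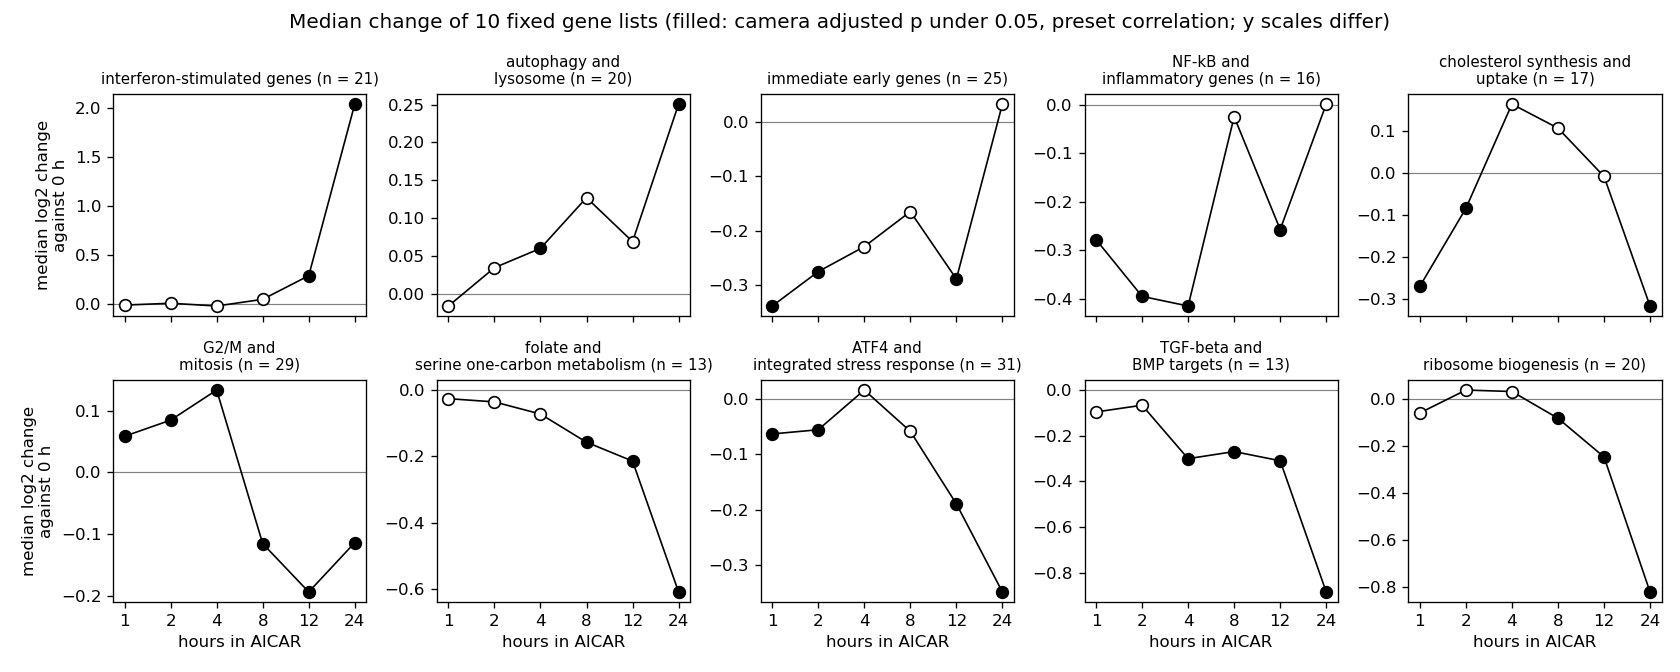
Median log2 change against 0 h (y axis, scales differ) of 10 gene lists fixed beforehand, at each time in AICAR (x axis, hours, evenly spaced); filled points passed camera's adjusted p of 0.05 with the preset correlation. The interferon median reached 2.04 at 24 h and that of ribosome biogenesis -0.82.

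Lats1 and Lats2 encode the kinases of the Hippo pathway that phosphorylate YAP and TAZ. Lats1 rose by 0.43 ± 0.07 at 4 h (SE, limma adjusted p = 0.000714) and by 0.66 ± 0.07 at 24 h. In between it stood 0.21 ± 0.08 above the controls at 8 h and 0.21 ± 0.07 at 12 h. A second Lats1 probe set rose by 1.24 ± 0.21 at 4 h and 1.46 ± 0.21 at 24 h, with 1.04 ± 0.23 at 8 h and 0.73 ± 0.21 at 12 h. The probe set standing for Lats2 fell by 0.62 ± 0.16 at 8 h, 0.61 ± 0.14 at 12 h and 0.56 ± 0.14 at 24 h, and its 8 h fall did not pass without AICAR 8h replicate 2 (-0.37) or control 0h replicate 3. Other Lats2 probe sets moved differently, and not all alike. The one with an _s_ suffix rose by 1.52 ± 0.23 at 1 h, 2.10 ± 0.23 at 2 h, 2.11 ± 0.23 at 4 h and 1.52 ± 0.26 at 8 h. One without a suffix, with a control signal of 5.19, near the background level of 5.08, rose by 1.53 ± 0.27 at 2 h and 1.63 ± 0.27 at 4 h. Another without a suffix, with a control signal of 6.82, differed by 0.16 at 4 h and did not pass at any time. A further one, with a control signal of 3.73, below the background level, differed by 0.04 at 4 h and did not pass at any time either. With the mean of its probe sets, Lats2 was 0.66 higher at 2 h, 0.34 higher at 8 h, where it did not pass, and -0.05 and -0.30 from the controls at 12 and 24 h, and Lats1 was 0.84 and 1.06 higher at 4 and 24 h. Of 24 Hippo components 9 fell and 4 rose at 24 h (9 and 4 adjusted over the list alone), and the list was not shifted (camera adjusted p = 0.0963). It was shifted down at 1 h alone (camera adjusted p = 0.0442; adjusted p = 0.814 with an estimated correlation), when 0 members fell or rose (1 fell adjusted over the list alone). Of 19 YAP and TAZ targets 12 fell and 1 rose at 24 h (12 and 1 adjusted over the list alone), with Ccn2 at -1.77, Gadd45b at -1.30 and Crim1 at -0.97, or -1.49 with the mean of its probe sets (camera adjusted p = 7.89e-05; adjusted p = 0.167 with an estimated correlation). This list was shifted down at each of the 6 times, but at none of them with an estimated correlation. The 6 comparisons share the 3 control arrays, so they are not independent of each other. Late minus early, which leaves out the controls, the list median was -0.0836. At 1 h 2 of its genes fell and 0 rose (3 fell adjusted over the list alone; camera adjusted p = 2.08e-06; adjusted p = 0.1002 with an estimated correlation).

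**Figure D4:**
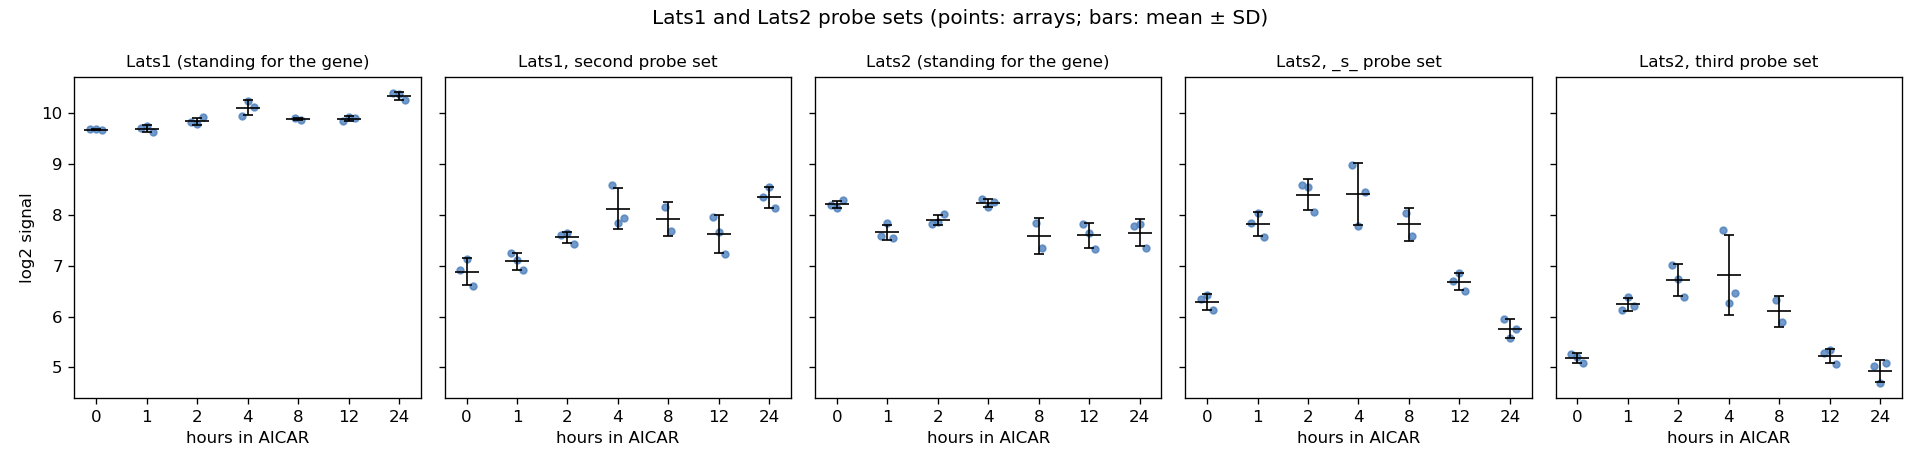
Log2 signal (y axis) of the Lats1 probe sets and some of the Lats2 probe sets against hours in AICAR (x axis, evenly spaced), with a point for each array and bars for mean ± SD. The Lats2 probe sets that differed by 0.16 and 0.04 at 4 h and passed at no time are not drawn. The Lats2 probe set with an _s_ suffix was 2.11 above the controls at 4 h, where the probe set standing for the gene differed by 0.03.

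The late times (8, 12 and 24 h) were compared with the early times (1, 2 and 4 h) without the 0 h arrays. Late minus early, 3744 genes were higher and 1843 lower, 5587 in all. Apol9a was higher by 2.23 ± 0.11 (SE), Pxylp1 by 1.84, Gbp2 by 1.75 and Xaf1 by 1.67 (0.89 with the mean of its probe sets), while Taf1d was lower by a log2 difference of -1.47 ± 0.10 (SE; -0.97 without AICAR 2h replicate 1) and the long non-coding gene Gas5 of -1.11. Of 30 lists 9 were shifted, 8 of them down. Late minus early, 20 of 21 interferon-stimulated genes were higher (20 adjusted over the list alone; adjusted p = 0.0343 with an estimated correlation), and 17 of 20 ribosome biogenesis genes were lower (17 adjusted over the list alone; adjusted p = 0.0343 with an estimated correlation). Of 13 folate and serine one-carbon genes 10 were lower (10 adjusted over the list alone; adjusted p = 0.0371 with an estimated correlation). These 3 lists held with an estimated correlation, and the other 6 did not. With the interquartile range covariate as well, 0 lists held. The late times did not move alike. Against 0 h, Ifit1 differed by 0.01, 0.84 and 4.99 at 8, 12 and 24 h, and Rtp4 by 0.33, 0.75 and 4.81. For these 2 interferon-induced genes the late mean rested mostly on 24 h. Over the 6 times against 0 h, 58 of 180 list and time pairs were shifted, and 0 held in camera with an estimated correlation, the lowest adjusted p being 0.0532, although 21 pairs had an unadjusted p under 0.05 there and fry called 39. Median, mean and test differed in sign at 24 h for 9 lists that were not shifted: G1 regulators, endoplasmic reticulum chaperones, NRF2 targets, fatty acid synthesis, glycolysis, oxidative phosphorylation, immediate early genes, NF-kB and inflammatory genes, and epithelial markers.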

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

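All tests of technical explanations in this part were chosen after the results were seen.

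The test of late against early times gave 5587 genes. The lists that differed were interferon-stimulated genes (median 0.96 late minus early), ribosome biogenesis (-0.36), TGF-beta and BMP targets (-0.35), folate and serine one-carbon metabolism (-0.26), extracellular matrix and myofibroblast genes (-0.18), G2/M and mitosis (-0.16), ATF4 and integrated stress response (-0.16), purine synthesis and salvage (-0.14), and YAP/TAZ targets (-0.0836). Of the 9 lists, 3 held with an estimated correlation (adjusted p between 0.0343 and 0.0371), and 0 with the interquartile range covariate as well. Among genes whose late and early arrays did not overlap, a limit that leaves out Rtp4 (1.86) and Ifit1 (1.85), those with the largest differences were Apol9a (2.23), Pxylp1 (1.84), Gbp2 (1.75), Xaf1 (1.67), Afap1l2 (1.56), Irgm2 (1.53), Ifih1 (1.49), Rhob (1.48), Nabp1 (1.47) and Zbtb4 (1.46) on the higher side. On the lower side were Taf1d (-1.47), Mir100hg (-1.43), H2bc4 (-1.28), H1f2 (-1.26), Rps15a (-1.26, by a probe set with a control signal of 5.69), Gas5 (-1.11), Id2 (-1.10), Zfp326 (-1.09) and Riok2 (-1.07). The median control signal of the 67 cytosolic ribosomal protein genes was 12.98, far above that of the Rps15a probe set, so which transcript this probe set measures is uncertain. In other splits of the 17 AICAR arrays, drawn with the real one to make 100, 1 gave as many genes as the 5587 of the real split, which was the real one, and the highest other gave 4450. For the 9 lists, 25 of 100 gave as many, the highest other 13. Those splits mix arrays of different times, which widens the spread within their groups alone, so they do not decide for either count. With each time kept whole there are 10 splits of the 6 times, too few for a share under 0.05. In 1 of 10, the real one, there were as many genes (highest other 3762), and in 8 of 10 there were as many lists (highest other 13).

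Among 8247 probe sets with no gene symbol or several that passed the filter, 1939 changed at 24 h against the controls. They stand outside the gene comparisons.

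The rise of interferon-stimulated genes at 24 h was examined against macrophages among the cells, array width and culture time. The median change of the 8 macrophage markers was 0.00743, against 2.04 for the list, although Cd68 rose by 1.08. Lyz2, abundant in macrophages, went from 3.86 to 3.93 and Ptprc from 4.05 to 4.15, both below the background level of 5.08. Csf1r and Cd14, above that level in the controls (5.77 and 6.38), differed by -0.21 and 0.02. This argues against a gain of macrophages as the source. A constant share of macrophages would leave the markers unchanged, so their changes do not test it. With each array's interquartile range as a covariate the list median was 2.02, which argues against array width as the whole cause. There were 0 untreated arrays at 24 h, so a rise with time in culture and a rise with AICAR cannot be told apart. Whether AICAR raised these genes stays open.

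The fall of immediate early genes at 1 h had a median of -0.34, and its highest median over quantile normalization, median centring and the interquartile range covariate was -0.30, which argues against array scaling or width. There were 0 untreated arrays at 1 h, so an effect of handling the cells without AICAR and an effect of AICAR cannot be told apart.

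At 4 h the Lats2 probe set with an _s_ suffix lay 2.08 above the change of the probe set standing for the gene. Of the Lats2 probe sets without a suffix, the one with the largest change rose by 1.63, from a control signal of 5.19, near the background level of 5.08. The others differed by 0.16, 0.04 and 0.03. Because that set was picked by its rise and the others did not rise past the test, this does not decide whether the suffixed set cross-hybridizes. With the interquartile range covariate the difference between the suffixed and the standing set was 2.17, which argues against array width. Different transcript forms and an effect of AICAR on them remain open, because 0 probe sets have a position on a transcript in the tables used here.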

How the results depend on the processing

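Array interquartile range as a covariate, alone and with an estimated correlation, and leaving out the 2 arrays with the highest medians were chosen after the data were seen. The results were the genes changed at 1h versus 0h, genes changed at 4h versus 0h, genes changed at 8h versus 0h, genes changed at 12h versus 0h, genes changed at 24h versus 0h, the same at 2 h, genes differing late minus early and genes differing among the 7 times. For counts that moved, the cause was not tested unless the setting itself tests fewer or more features, uses fewer arrays or sets a stricter threshold. Quantile normalization gave 110, 353 and 2083 genes at 1, 2 and 8 h, and median centring 781 at 8 h. With array weights, whose fit stopped before converging, counts at 1, 2, 4, 8 and 12 h were 421, 1338, 7476, 2371 and 4645, and 10636 differed among the 7 times. The interquartile range covariate gave 153, 618 and 2418 at 1, 2 and 8 h. Without the 2 arrays with the highest medians, 126 changed at 2 h. Each probe set on its own gave 94, 2465, 2008, 5091 and 9517 probe sets at 1, 4, 8, 12 and 24 h, 10420 late minus early and 11160 among the 7 times. At adjusted p under 0.01 the counts at 1, 2, 4, 8 and 12 h were 34, 71, 751, 551 and 1914. With a 2-fold minimum, counts at 1, 2, 4, 8, 12 and 24 h were 11, 21, 46, 32, 117 and 499, with 108 late minus early and 561 among the 7 times. The fit of the 2 groups compared gave 194 at 1 h. With an estimated correlation 0 list and time pairs passed against 0 h and 3 lists late minus early; with the covariate as well, 0 and 0. Fry, which does not compare a list with other genes, gave 19 lists late minus early.

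The replicate number as a block gave 107, 386 and 2428 genes at 1, 2 and 4 h and moved no other count by over 1.5 times. Of 17 same-number pairs 10 had a correlation of deviations over 0.1; since not every pair did and the labels give the number no meaning, it was not used to pair the arrays. As a hint from the data, 13 of 20 arrays correlated best with their own number, including 6 of 6 numbered 3. The largest component of the spread within groups held 49.3% of it and followed the arrays' interquartile range, and the 6 arrays numbered 3 lay on its narrow side, with AICAR 4h and 8h replicates 2. What these arrays share was not tested.

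The share of higher genes at 1 h was 1.61% and became 23.6% with quantile normalization; with the covariate 23 of 153 were higher. At 2 h it was 32.1%, 21.3% with median centring and 48.4% with the covariate, and at 4 h 42.9%, 30.7% and 54.3%.

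Leaving out each array in turn gave 18 to 60 genes at 1 h, 78 to 132 at 2 h, 904 to 1399 at 4 h, 250 to 1018 at 8 h, 2126 to 3127 at 12 h, 4478 to 5104 at 24 h, 5615 to 6392 among the 7 times and 4929 to 5896 late minus early, with 52 to 60 list pairs and 8 to 10 lists. The lowest values came without AICAR 1h replicate 3 at 1 h and AICAR 8h replicate 1 at 8 h; a lone 8 h array was assumed to vary like the other groups.

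With the mean of all probe sets, the sign turned for Lats2 at 2 h (0.66) and 8 h (0.34), Cenpe at 4 h (-0.26), Ptgs2 at 8 h (0.0343) and Clock at 24 h (-0.0458); without _x_ and _s_ probe sets it turned for Ccdc28b (-0.10) and Fnip1 (-0.0192) at 12 h. These settings use other probe sets. Over all alternatives, named-gene values kept their side of the threshold 14343 times, lost it 726 times, gained it 120 times and turned 7 times, and list calls were kept 1114 times and lost 250 times. Values that passed in neither setting were counted as kept whatever their sign, so turns among them are not listed here. Signal near the non-specific controls limits dim genes.

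With 3 arrays against 3 there are 10 splits, too few for a share under 0.05; in 1 of 10, the real one, the count was as large, with real counts of 62, 190, 1564, 3068 and 5229 at 1, 2, 4, 12 and 24 h and 0 as the highest other. Over 100 draws, 1, the real one, gave as many genes as the 6260 among the 7 times (highest other 32). At a share of 0.05 this excludes only freely exchangeable arrays that do not differ by time, as the draws suppose. The labels do not say whether arrays of the same time came from separate cultures. The draws therefore cannot exclude chance differences between cultures. Of the same draws 4, the real one included, gave as many as the 58 list pairs with the preset correlation (highest other 71), a share under 0.05, but 0 pairs held with an estimated correlation, so the draws are not taken to support any single list.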

Other observations

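The 9 families in this part were chosen by symbol after the results were seen, because members had been seen to move, so their counts and medians are not independent evidence of a direction. Of 20 histone genes, which include the variant genes H2az1, H2az2, H3f3a and H3f3b, 10 fell and 0 rose at 24 h (median -0.21). Of 9 snoRNA host genes, 6 fell and 0 rose at 24 h (median -0.80), and 6 fell and 1 rose at 8 h. Of 9 guanylate-binding protein and immunity-related GTPase genes, some of which also stand in the interferon list, 7 rose and 0 fell at 24 h (median 2.04). Of 30 aminoacyl-tRNA synthetase genes, which charge tRNAs, 13 fell and 3 rose at 24 h (median -0.17). Of 12 Klf genes, 2 fell and 0 rose at 1 h (median -0.24), whereas 5 rose and 1 fell at 4 h (median 0.25), and 3 rose and 3 fell at 24 h. At 24 h 85 of 257 Zfp-named zinc finger genes rose and 23 fell (median 0.11, camera adjusted p = 0.243). Of 38 Trim genes 18 rose and 2 fell (median 0.18), and of 20 Dusp phosphatase genes 5 rose and 7 fell (median -0.08). Among 67 cytosolic ribosomal protein genes 1 rose and 4 fell. For comparison, 3342 of all 12944 genes tested rose and 1887 fell at 24 h. The medians given kept their sign under quantile normalization, median centring and the interquartile range covariate.

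Probe sets for the type I interferon genes Ifnb1, Ifna4 and Ifna2, also named after their values were seen, gave signals of 4.95, 5.33 and 5.74 in the controls and 5.02, 5.15 and 5.68 at 24 h, against a 95th percentile of 5.08 for the non-specific control probe sets. Ifnb1 lay below that level and Ifna4 near it, so these values do not show whether the transcripts of these 2 genes changed. Ifna2 differed by -0.06 ± 0.14 (SE) at 24 h and did not pass the test. A Prkaa2 probe set other than the one standing for the gene had a control signal of 4.68, below that level, and signals of 5.56 at 8 h, 5.50 at 12 h and 5.59 at 24 h, so its rise gives no exact fold of the transcript. Of 4876 genes with several probe sets, 127 had probe sets called in opposite directions at 24 h.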
